A study of Mus musculus with 9 samples.

How the data were processed

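RNA was sequenced from retinas of C57BL/6 mice at postnatal day 17. Oxygen-induced retinopathy (OIR) is a mouse model in which newborn pups breathe high oxygen, which stops the growth of retinal vessels and prunes them, and then return to room air, where the poorly perfused retina becomes hypoxic and forms new vessels. The labels put 9 libraries into 3 groups of 3: wild-type mice kept in room air (RA WT), wild-type mice with retinopathy (OIR WT) and IL-19 knockout mice with retinopathy (OIR KO). Knockout retinas from room air were not analysed here, so genotype could be compared only within retinopathy. Nothing in the labels says whether the samples of a group were separate animals beyond being separate samples, so p-values measure the spread between these samples, which may be technical. For RA WT and OIR KO, the Y-linked genes given below argue against a spread that is only technical.

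Per the labels' protocols, RNA was extracted from frozen retinas with Trizol and made into libraries with an NEBNext Ultra kit. Per the submitters' processing notes, HISAT2 and the mouse build GRCm38 were used. The version of HISAT2, the program that assembled and quantified the genes, the strand setting and the annotation release are not given in the sources used here. The authors deposited 1 table of FPKM values, fragments scaled by gene length and by the number of mapped fragments, with 1 column per library. The table held 25108 genes and gene models, of which 22036 had an Ensembl ID and 3072 were new models without an ID or a position. Of the Ensembl IDs, 22022 matched the GENCODE M21 annotation of GRCm38, which gave the coordinates. Symbols came from the table; 19 symbols stood on more than 1 entry, and the entry with the highest mean kept the plain symbol. A total of 3841 entries were at 0 in every library. An exact 0 in such a table can be a failed estimate, so a gene is described as listed at 0. Without strand information, reads of a gene and of an overlapping antisense gene cannot be told apart, and values of near-identical gene copies are uncertain singly.

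The depth of the libraries is not given in the sources used here. Column totals of FPKM lay between 344876 and 366536 and are no measure of depth. Among 4521 genes with 1 annotated transcript, the smallest step of FPKM times transcript length gave relative depths from 0.853 of the mean (RA WT 2) to 1.139 (OIR KO 2), a ratio of 1.336 between the deepest and the shallowest library. Of the low values, up to 20 steps, 26.2 to 28.9% per library lay within 0.02 of a whole step, so reads could not be recovered, no count model was run, and no counting interval or floor is given.

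Values were taken as log2(FPKM + 0.5) with no further scaling. A fold change on this scale understates the change of genes with low FPKM. Genes with an FPKM of at least 0.5 in at least 3 of the 9 libraries were kept (15678). The linear model of limma 3.58.1 in R 4.3.3 was fitted to all 9 libraries with 1 mean per group, without covariates, with empirical Bayes moderation using the mean-variance trend and the robust option. Each of the 3 comparisons between groups was tested on both sides with Benjamini-Hochberg adjustment over all kept genes, and a gene with an adjusted p under 0.05 was called. The level of Il19 was compared with exact two-sided permutation tests, for which 3 against 3 libraries cannot give a p under 0.1.

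Gene lists were tested with camera of limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 26 lists with at least 3 kept members. The lists covered hypoxia response and glycolysis; tip cells and neovascular endothelium; pan-endothelial markers; pericytes and smooth muscle; microglia and macrophages; alternative macrophage activation; proinflammatory cytokines and chemokines; the interleukin-10 family and its receptors; the interferon response; complement; reactive gliosis and STAT3 targets; markers of Müller, rod, cone, bipolar, amacrine, horizontal and retinal ganglion cells; the cell cycle; extracellular matrix and remodelling; cholesterol synthesis; immediate early genes; markers of retinal pigment epithelium, lens, erythrocytes, neutrophils and lymphocytes, and ciliary body, iris and cornea; mitochondrially encoded genes; and sex-linked genes as a check. Members were counted by the gene test adjusted over all genes, and again with the p-values adjusted over the list alone. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were run beside it. No list was called in any comparison with an estimated correlation.

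The genes named in the text followed a rule: the measured members of the interleukin-10 family list; per comparison the 5 risen and the 5 fallen genes with the largest change among those called, with a mean of at least 1 FPKM and no overlap between the groups, filled up with the genes of smallest p where fewer than 5 passed, leaving out models without an ordinary symbol; per list the 3 called members with the largest change, or, where fewer passed, the members of smallest p up to 2; the sex-linked genes and Nnt, which differs between substrains of C57BL/6; and the called genes on chromosome 1 near Il19. Where a list had 5 or fewer called members in a direction, the members outside the rule were also named, after their values were seen. The text does not name every gene the rule gives: it names 56 of 76 called genes for OIR WT against RA WT, 11 of 11 for OIR KO against OIR WT and 37 of 62 for OIR KO against RA WT. That choice was made after their values, and how they fared without single libraries, were seen, so the named genes may look steadier than the rest; the counts of calls kept and lost cover all called genes of the rule. The gene filter, tests, groups, lists, named-gene rule and the other settings, apart from those named as added later, were fixed before the data were examined.

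The other settings were other pseudocounts, other filters on low values, rescaling to equal totals, quantile and median-of-ratios scaling, the variance model without trend and robust option, array weights, the replicate number as a block, a covariate made from Y-linked genes, fits of only the 2 groups compared, other list tests and leaving out each library in turn. Fits of only Ensembl genes, fits without the 2 libraries with the most lens RNA and a gliosis covariate were added after seeing the data. The shift of the knockout libraries back towards room air was measured on genes called with 2 OIR WT libraries against the held-out OIR WT library, in 3 rotations. For the overlap of the 2 comparisons that share the RA WT libraries, unchanged groups were simulated against shared controls 100 times for the correlation, sign and covariance and 10 times for the shared calls.

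The model was tested on simulated data with known changes before it was run on the table. For OIR WT against RA WT, with 15408 genes tested, 76.5% of 98 genes changed by 1 on the log2 scale and 93.9% of 99 genes changed by 2 were recovered, and 11 unchanged genes were called. For OIR KO against OIR WT, with 15416 genes tested, the shares were 78.6% and 96.9% of 98 genes each, with 10 unchanged genes called. For OIR KO against RA WT, with 15398 genes tested, 78.8% of 99 and 95.9% of 97 genes were recovered, with 6 unchanged genes called. In each simulation the 1 shifted list was called and 0 other lists. The simulated genes were drawn independently of one another. The simulations therefore do not test how the list calls fare where genes of a list are correlated. Nor do they test how many unchanged genes are called where many genes differ together between libraries of a group.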

Results

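Retinal RNA was compared at postnatal day 17 between mice kept in room air, wild-type mice with oxygen-induced retinopathy and IL-19 knockout mice with retinopathy, with 3 libraries per group. Of the 25108 genes and gene models in the FPKM table, 15678 passed the filter on low values and were tested. Absolute depth is unknown, and relative depth lay between 0.853 and 1.139 of the mean. Across genes, which are not independent replicates, libraries of the same group correlated with r from 0.974 to 0.985. The leading principal component held 47.2% of the variance and placed the RA WT libraries between -37.2 and -35.9, the OIR WT libraries at 28.9, 11.7 and 31.3, and OIR KO 1, 2 and 3 at 7.96, 32.5 and -3.3. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in RA WT 2 and OIR KO 1, and Ddx3y was 6.80 FPKM in RA WT 3 against 12.9 to 15.7 FPKM in the other 6 libraries. These Y-linked values argue against the samples of RA WT, or those of OIR KO, all being repeats of the same animal or pool. For OIR WT this stays open. Cryaa, a crystallin abundant in the lens, was at 11.6 FPKM in RA WT 1 and 7.68 FPKM in OIR KO 2, and at most 2.17 FPKM in the other libraries. Below, values are mean FPKM ± SD with n = 3 libraries per group, and log2 changes are on the log2(FPKM + 0.5) scale with their standard error (SE).

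Il19, the targeted gene (ENSMUSG00000016524, GRCm38 chromosome 1, 130932656 to 130940115, minus strand), was listed at 0 in every OIR KO library. It was also listed at 0 in the wild-type libraries except RA WT 1, at 0.0406 FPKM, so its level did not separate the genotypes (exact two-sided permutation p = 1 for each pair of groups, n = 3, where 0.1 is the smallest possible). Il10, Il20, Il24 and Ifnl3 were listed at 0 in all 9 libraries. Ifnl2 was above 0 only in RA WT 2 (0.0407 FPKM) and Il22ra1 only in OIR WT 2 (0.0197 FPKM). Il22ra2 did not exceed 0.0387 FPKM and Ifnlr1 did not exceed 0.285 FPKM in any library. Il22 lay between 0.280 and 1.11 FPKM, Il10ra between 0.188 and 0.571 FPKM and Il20rb between 0.0973 and 0.487 FPKM. Il10rb, a receptor chain shared by several of these cytokines, was at 2.69 ± 0.334 FPKM in RA WT, 3.30 ± 0.504 in OIR WT and 3.25 ± 0.565 in OIR KO, with log2 differences of 0.25 for OIR WT against RA WT (adjusted p = 0.327) and -0.02 for OIR KO against OIR WT (adjusted p = 0.984). Il20ra, which with Il20rb forms the receptor of IL-19, fell from 0.778 ± 0.137 FPKM in RA WT to 0.159 ± 0.0604 FPKM in OIR WT (log2 -0.96, SE 0.21, adjusted p = 0.0166), and it also fell when adjusted over the list alone. That call was lost without RA WT 2 (adjusted p = 0.0545), RA WT 3 (0.0611) or OIR WT 1 (0.0651). Il20ra was at 0.327 ± 0.220 FPKM in OIR KO, which passed the test neither against OIR WT (log2 0.30, adjusted p = 0.703) nor against RA WT (log2 -0.66, adjusted p = 0.0788), although it was lower than in RA WT when adjusted over the list alone. Only 2 members of this list were tested, so that adjustment is slight.

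The comparison of OIR WT with RA WT asks what retinopathy does to the wild-type retina. Edn2, the peptide endothelin 2 made by stressed photoreceptors, rose from 0.835 ± 0.467 FPKM in RA WT to 90.1 ± 46.4 FPKM in OIR WT (log2 5.96, SE 0.72, adjusted p = 0.00293). Adm, the vasodilator adrenomedullin and a target of hypoxia-inducible factors, rose from 0.726 ± 0.156 to 31.6 ± 2.88 FPKM (log2 4.71, SE 0.37, adjusted p = 0.000505). Ndufa4l2, a mitochondrial protein induced by hypoxia, rose from 5.36 ± 1.07 to 141 ± 19.2 FPKM (log2 4.61, SE 0.20, adjusted p = 1.42e-05). Slco1a4 and Slco1c1, transporters of the blood-retinal barrier, fell from 7.0 ± 0.644 to 0.864 ± 0.208 FPKM (log2 -2.47, SE 0.15) and from 3.53 ± 0.532 to 0.426 ± 0.177 FPKM (log2 -2.13, SE 0.19). Lad1 (log2 4.62) and Bcl3, a regulator of NF-kappaB (log2 4.55), completed the 5 leading risen genes, and Fam107a (log2 -2.86), Spc25 (log2 -2.37) and Etnppl (log2 -2.17) the 5 leading fallen genes. The Bcl3 call was lost without RA WT 2 (adjusted p = 0.0516) or OIR WT 1 (0.0521).

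In total 2503 genes changed, 1261 upwards and 1242 downwards, of which 479 rose and 151 fell at least 2-fold. Groups did not overlap in 35% of the genes tested, where chance gives 10%. The number of changed genes was 1437 without RA WT 2, 1391 without RA WT 3, 1039 without OIR WT 1 and 1331 without OIR WT 3, against 2093 without RA WT 1 and 2164 without OIR WT 2. With a covariate made from Y-linked genes it was 1581. Of 26 lists, 22 were called, 13 upwards and 9 downwards. With an estimated correlation 0 lists were called, and fry called 19.

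Most genes of the hypoxia response and glycolysis list rose. In OIR WT, 27 of the 36 members rose and 0 fell, with 29 risen and 1 fallen when adjusted over the list alone, and the median log2 change was 0.80 (camera adjusted p = 5.87e-17; adjusted p = 0.194 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, rose from 1.72 ± 0.328 to 20.1 ± 5.65 FPKM (log2 3.19, SE 0.41, adjusted p = 0.00324). Vegfa, the main growth factor of new vessels, rose from 67.1 ± 4.12 to 271 ± 5.92 FPKM (log2 2.01, SE 0.14, adjusted p = 0.000111).

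Markers of tip cells and neovascular endothelium rose in 21 of 27 members, or 23 when adjusted over the list alone, with a median of 1.37 (camera adjusted p = 5.87e-17; adjusted p = 0.194 with an estimated correlation). Apln, a ligand made by tip cells, rose from 2.53 ± 0.430 to 36.2 ± 11.5 FPKM (log2 3.55, SE 0.33, adjusted p = 0.00102), and Esm1 from 0.0399 ± 0.0158 to 6.68 ± 3.29 FPKM (log2 3.64, SE 0.48, adjusted p = 0.00338). Pan-endothelial markers went both ways, with 6 of 22 risen and 4 fallen (11 risen and 6 fallen when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.388; adjusted p = 0.767 with an estimated correlation). Emcn rose from 1.66 ± 0.379 to 5.72 ± 1.90 FPKM (log2 1.49). The 4 fallen members were Ly6c1 (from 17.0 ± 1.31 to 3.69 ± 0.848 FPKM, log2 -2.08), Slco1a4, the drug transporter gene Abcb1a (log2 -1.22) and Tek (log2 -0.95). The Tek call was lost without RA WT 3 (adjusted p = 0.0588) or OIR WT 3 (0.0508). Pericyte and smooth muscle markers rose in 8 of 15 members, or 10 when adjusted over the list alone. The pericyte list had a median of 0.77 (camera adjusted p = 1.64e-05; adjusted p = 0.194 with an estimated correlation). Acta2, smooth muscle actin, rose from 4.74 ± 1.55 to 27.1 ± 8.92 FPKM (log2 2.40), and Higd1b, a pericyte gene, from 2.31 ± 0.360 to 9.03 ± 0.672 FPKM (log2 1.77).

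**Figure D1:**
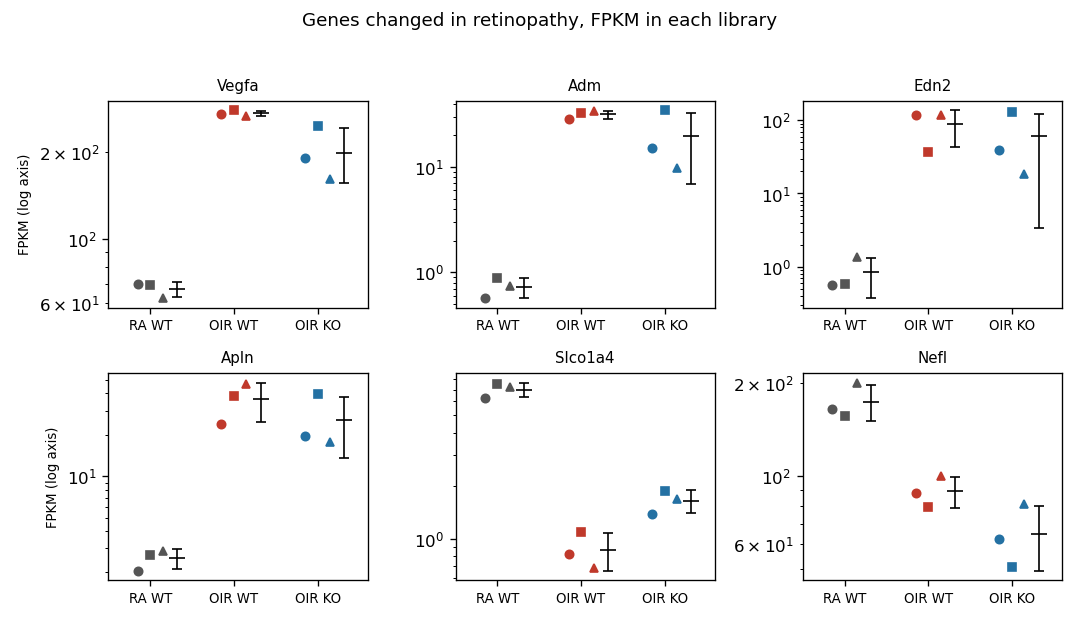
FPKM (log axis) of 6 genes in each library of RA WT, OIR WT and OIR KO; circles, squares and triangles stand for replicates 1, 2 and 3, and bars for the mean ± SD of a group. Vegfa, Adm, Edn2 and Apln lie higher in every OIR library than in every RA WT library, and Slco1a4 and Nefl lie lower.

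Part of the immune cell genes rose as well. Of 26 microglia and macrophage markers, 17 rose (19 when adjusted over the list alone), with a median of 1.04 (camera adjusted p = 3.69e-12; adjusted p = 0.194 with an estimated correlation). Lyz2, lysozyme, rose from 0.733 ± 0.119 to 6.67 ± 1.12 FPKM (log2 2.53, SE 0.26), and Cd68, a lysosomal macrophage marker, from 1.52 ± 0.541 to 6.46 ± 2.07 FPKM (log2 1.77, SE 0.32). Complement genes rose in 11 of 18 members, or 12 when adjusted over the list alone. The complement list had a median of 0.90 (camera adjusted p = 4.68e-06; adjusted p = 0.194 with an estimated correlation). Its leading member C4b rose from 0.556 ± 0.265 to 8.73 ± 0.985 FPKM (log2 3.15). Interferon response genes rose in 10 of 28 members by either adjustment, over all genes or adjusted over the list alone. The interferon list had a median of 0.64 (camera adjusted p = 8.51e-07; adjusted p = 0.306 with an estimated correlation), and Irf7 rose from 7.12 ± 0.0816 to 20.5 ± 3.48 FPKM (log2 1.45). Proinflammatory cytokines and chemokines rose in 7 of 13 members, with 8 risen and 1 fallen when adjusted over the list alone. The median was 1.27 (camera adjusted p = 0.00157; adjusted p = 0.299 with an estimated correlation), and the chemokine Ccl3 rose from 0.0249 ± 0.0431 to 1.61 ± 0.526 FPKM (log2 1.98). The chemokine gene Ccl2 was listed at 0 in RA WT and rose to 3.49 ± 2.56 FPKM, a call lost without RA WT 1, RA WT 2, RA WT 3, OIR WT 1 or OIR WT 3 (0.0912 to 0.137). Of 21 genes of alternative macrophage activation, 6 passed the filter on low values. Among these 6, Stab1 (log2 1.37) and Tgfb1 (log2 1.43) rose, with 3 risen when adjusted over the list alone (camera adjusted p = 0.0187; adjusted p = 0.269 with an estimated correlation). The Tgfb1 call was lost without OIR WT 1 (adjusted p = 0.0508), and the list's call without OIR WT 3 (0.0545). Of 19 neutrophil and lymphocyte genes with values, only Cd8a passed the filter on low values. Cd8a rose from 0.396 ± 0.101 to 0.902 ± 0.0456 FPKM (log2 0.65), a call lost without RA WT 1 (adjusted p = 0.0556), OIR WT 1 (0.0726) or OIR WT 3 (0.0625).

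Reactive gliosis genes and STAT3 targets rose in 23 of 33 members, or 25 when adjusted over the list alone, with a median of 2.14 (camera adjusted p = 9.41e-13; adjusted p = 0.217 with an estimated correlation). Serpina3n, an acute-phase protease inhibitor of reactive glia, rose from 1.61 ± 1.25 to 50.9 ± 30.5 FPKM (log2 4.50, SE 0.97), a call lost without RA WT 1 (adjusted p = 0.0590), RA WT 2 (0.0698), OIR WT 1 (0.0693) or OIR WT 3 (0.0652). Markers of Müller glia, the radial glia of the retina, went both ways, with 10 of 20 fallen and 3 risen, or 11 and 3 when adjusted over the list alone. The Müller list had a median of -0.57 (camera adjusted p = 0.000289; adjusted p = 0.194 with an estimated correlation). Abca8a fell from 39.5 ± 5.13 to 13.1 ± 4.23 FPKM (log2 -1.59, SE 0.21). The risen members were Cyr61, a matricellular protein (from 2.57 ± 0.765 to 21.2 ± 8.07 FPKM, log2 2.77), the transcription factor Sox9 (log2 1.29) and Crym (log2 1.75). The Crym call was lost without RA WT 1 (adjusted p = 0.0605), RA WT 2 (0.0512), RA WT 3 (0.0504), OIR WT 1 (0.0767) or OIR WT 3 (0.0734).

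Part of the markers of ganglion, amacrine and bipolar cells fell. Of 22 retinal ganglion cell markers, 13 fell and 0 rose (16 fallen when adjusted over the list alone), with a median of -0.64 (camera adjusted p = 8.59e-09; adjusted p = 0.194 with an estimated correlation). Nefl, the neurofilament light chain, fell from 174 ± 23.4 to 89.1 ± 10.4 FPKM (log2 -0.96, SE 0.17), and Chrna6, a nicotinic receptor subunit, from 39.8 ± 4.62 to 15.9 ± 0.712 FPKM (log2 -1.29, SE 0.17). Amacrine cell markers fell in 14 of 25 members and 1 rose, or 16 and 1 when adjusted over the list alone. The amacrine list had a median of -0.45 (camera adjusted p = 1.61e-08; adjusted p = 0.194 with an estimated correlation). Cartpt, a neuropeptide, fell from 82.0 ± 15.7 to 35.9 ± 3.44 FPKM (log2 -1.17), while Npy was the risen member (log2 0.54). The Npy call was lost without RA WT 1 (adjusted p = 0.114), RA WT 2 (0.0515), RA WT 3 (0.109), OIR WT 1 (0.145) or OIR WT 3 (0.131). Bipolar cell markers fell in 12 of 26 members and 0 rose, or 16 and 1 when adjusted over the list alone. The bipolar list had a median of -0.42 (camera adjusted p = 6.01e-07; adjusted p = 0.194 with an estimated correlation). The tachykinin receptor gene Tacr3 fell from 7.40 ± 0.266 to 3.22 ± 0.429 FPKM (log2 -1.09). The horizontal cell list did not pass (camera adjusted p = 0.0701; adjusted p = 0.194 with an estimated correlation). Of its 12 members 4 fell, Calb1 (log2 -0.60), Slc4a3 (log2 -0.59), Sept4 (log2 -0.59) and Nefm (log2 -0.87). When adjusted over the list alone, 5 fell and 1 rose. Calb1 was not called without OIR WT 1 (adjusted p = 0.0535). Sept4 was not called without RA WT 2, RA WT 3, OIR WT 1 or OIR WT 3 (0.0712 to 0.0884), and Nefm not without any 1 of the 6 libraries (0.0616 to 0.134).

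Few photoreceptor markers changed. Of 26 rod markers 1 fell, Guca1b, from 541 ± 28.3 to 418 ± 14.2 FPKM (log2 -0.37, SE 0.08), also when adjusted over the list alone. The rod list did not pass (median -0.04, camera adjusted p = 0.636; adjusted p = 0.888 with an estimated correlation). The Guca1b call was lost without OIR WT 1 (adjusted p = 0.0736) or OIR WT 3 (0.0658). Of 17 cone markers, Gnb3 rose (log2 1.04) and Arr3 (log2 -0.87), Rxrg (log2 -0.61) and Slc24a2 (log2 -0.53) fell, with 1 risen and 4 fallen when adjusted over the list alone. The cone list had a median of -0.17 (camera adjusted p = 0.0341; adjusted p = 0.433 with an estimated correlation). The cone list was not called without RA WT 1 (adjusted p = 0.105), OIR WT 1 (0.157) or OIR WT 3 (0.0729). Slc24a2 kept its call without each library in turn. Gnb3 lost it without RA WT 1, RA WT 2, RA WT 3, OIR WT 1 or OIR WT 3 (0.0925 to 0.148). Arr3 lost it without RA WT 1, RA WT 2, OIR WT 1 or OIR WT 3 (0.0523 to 0.0890). Rxrg lost it without RA WT 2, RA WT 3, OIR WT 1 or OIR WT 3 (0.0577 to 0.0926).

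Part of the proliferation and matrix genes rose. Of 22 cell cycle genes, 15 rose by either adjustment, over all genes or adjusted over the list alone. The median was 0.91 (camera adjusted p = 1.61e-08; adjusted p = 0.194 with an estimated correlation), and Top2a, a topoisomerase of dividing cells, rose from 0.0619 ± 0.0330 to 0.997 ± 0.192 FPKM (log2 1.41). Extracellular matrix genes rose in 16 of 33 members and 1 fell, or 23 and 1 when adjusted over the list alone. The matrix list had a median of 0.67 (camera adjusted p = 8.37e-10; adjusted p = 0.206 with an estimated correlation). Col1a1, a fibrillar collagen, rose from 0.294 ± 0.0763 to 3.83 ± 0.693 FPKM (log2 2.44). The fallen member was the protease gene Mmp9 (log2 -0.68). Immediate early genes rose in 14 of 20 members, or 15 when adjusted over the list alone. The median was 1.08 (camera adjusted p = 3.91e-08; adjusted p = 0.194 with an estimated correlation), and Atf3 rose from 1.74 ± 0.418 to 14.7 ± 6.38 FPKM (log2 2.68). Cholesterol synthesis genes fell in 7 of 24 members by either adjustment, over all genes or adjusted over the list alone. The cholesterol list had a median of -0.31 (camera adjusted p = 6.39e-07; adjusted p = 0.194 with an estimated correlation). Insig1 fell from 25.3 ± 2.59 to 10.6 ± 0.336 FPKM (log2 -1.21).

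Erythrocyte markers rose in 5 of 8 members, with 5 risen and 1 fallen when adjusted over the list alone. The erythrocyte list had a median of 2.62 (camera adjusted p = 0.0214; adjusted p = 0.386 with an estimated correlation). They were the globins Hbb-bs (from 33.2 ± 10.6 to 365 ± 186 FPKM, log2 3.31), Hbb-bt, Hba-a1 and Hba-a2, and Alas2. No globin call held without each library in turn: Hba-a1, Hba-a2 and Hbb-bt were lost without any 1 of the 6 libraries (adjusted p = 0.0517 to 0.135). Hbb-bs (0.0813 to 0.120) and Alas2 (0.0611 to 0.0981) were lost without each but OIR WT 2. The list's call was lost without RA WT 1 (0.0502) or OIR WT 3 (0.0729). Few markers of tissues next to the retina fell. Retinal pigment epithelium markers had 1 of 14 fallen, Rgr (log2 -1.10), and 0 when adjusted over the list alone. The pigment epithelium list was called (camera adjusted p = 0.0215; adjusted p = 0.438 with an estimated correlation) but not without RA WT 3 (0.233) or OIR WT 1 (0.0972). Rgr lost its call without RA WT 1, RA WT 2, RA WT 3, OIR WT 1 or OIR WT 3 (0.0781 to 0.132). Lens markers had 1 of 12 fallen by either adjustment, over all genes or adjusted over the list alone, Bfsp2 (log2 -1.30, SE 0.24). The lens list was called (camera adjusted p = 0.0381; adjusted p = 0.476 with an estimated correlation) but not without RA WT 1 (0.393), OIR WT 1 (0.0529) or OIR WT 3 (0.0545). Ciliary body, iris and cornea markers had 3 of 13 fallen, Col9a1 (log2 -1.05), Ltbp2 (log2 -0.86) and Opn4 (log2 -0.76), or 4 when adjusted over the list alone. Opn4 is also the melanopsin gene of intrinsically photosensitive ganglion cells, so its fall need not come from tissue next to the retina. The ciliary list was called (camera adjusted p = 0.00701; adjusted p = 0.217 with an estimated correlation). Col9a1 lost its call without RA WT 2, RA WT 3, OIR WT 1 or OIR WT 3 (0.0745 to 0.0819). Ltbp2 lost it without each library but RA WT 1 (0.0724 to 0.153) and Opn4 without any 1 library (0.0599 to 0.124). Of 13 mitochondrially encoded genes 1 fell, mt-Nd2 (log2 -0.54), and 0 when adjusted over the list alone. The mitochondrial list did not pass (camera adjusted p = 0.0906; adjusted p = 0.628 with an estimated correlation), and mt-Nd2 was not called without any library but RA WT 3 (0.0752 to 0.0972).

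The comparison of OIR KO with OIR WT asks what the lack of IL-19 does within retinopathy. Bnip3, a mitophagy receptor and target of hypoxia-inducible factors, was lower in OIR KO, at 94.2 ± 20.4 FPKM against 184 ± 16.0 in OIR WT and 66.0 ± 2.24 in RA WT (log2 -0.98, SE 0.14, adjusted p = 0.0377). Hif3a, a member of the same factor family, was higher, at 5.19 ± 0.223 FPKM against 1.95 ± 0.330 in OIR WT and 4.11 ± 0.471 in RA WT (log2 1.23, SE 0.13, adjusted p = 0.00610). Rab22a, a GTPase of endosomes, was also higher, at 6.40 ± 0.508 FPKM against 2.10 ± 0.291 in OIR WT and 7.0 ± 0.527 in RA WT (log2 1.41, SE 0.12, adjusted p = 0.00205). For both genes, the OIR KO mean lay nearer to the RA WT mean than the OIR WT mean did. Crb1, a polarity protein of photoreceptors and Müller glia, was lower, at 31.1 ± 2.12 FPKM against 61.2 ± 4.88 in OIR WT and 58.8 ± 4.16 in RA WT (log2 -0.97, SE 0.09, adjusted p = 0.00334). Vps39, a subunit of a lysosomal tethering complex, was lower, at 9.63 ± 0.505 FPKM against 18.4 ± 1.15 in OIR WT and 18.2 ± 0.413 in RA WT (log2 -0.90, SE 0.08, adjusted p = 0.00250).

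The other leading genes were higher for Ip6k2 (log2 0.95, SE 0.13), Usp2 (log2 0.64, SE 0.10) and Dynlt1b (log2 0.54, SE 0.08), and lower for Entpd4b, from a family of near-identical copies, at 11.1 ± 0.552 FPKM against 29.3 ± 4.21 in OIR WT and 23.8 ± 1.55 in RA WT (log2 -1.36, SE 0.11). Tmem254a, also from a family of copies, was listed at 0 in every OIR KO and RA WT library and at 4.31 ± 1.35 FPKM in OIR WT. The summed Tmem254 copies were at 24.3 ± 17.0 FPKM in RA WT, 24.6 ± 4.04 in OIR WT and 8.69 ± 1.54 in OIR KO. The single entry therefore does not show that the family rose in OIR WT. In total 21 genes differed, 9 higher and 12 lower in OIR KO, of which 5 and 8 at least 2-fold, and 5 had no Ensembl ID. At an unadjusted p under 0.05 there were 1554 genes, where 784 are due by chance, and groups did not overlap in 17.7% of genes, where chance gives 10%. A split of the same 6 libraries that mixed the genotypes called 348 genes, so these excesses alone do not show an effect of genotype. Between the real groups, the count of called genes was 10 without OIR KO 1, 42 without OIR KO 2, 11 without OIR KO 3, 8 without OIR WT 1, 18 without OIR WT 2 and 7 without OIR WT 3. It was 459 with array weights and 8 with the replicate number as a block. Of the 21 genes, 7 were called without each library in turn, among them Entpd4b, Vps39, Rab22a and Crb1. Bnip3 was called only without OIR KO 2 (adjusted p = 0.0739 to 0.191 otherwise). Hif3a was not called without OIR KO 1 (0.0525), OIR WT 1 (0.0530) or OIR WT 3 (0.0543). Ip6k2 was not called without OIR KO 1, OIR KO 3, OIR WT 1 or OIR WT 3 (0.116 to 0.160), and Usp2 and Dynlt1b not without any 1 library (0.0566 to 0.254). Tmem254a had too few libraries above the filter to be tested without OIR WT 1, 2 or 3. On chromosome 1 near Il19, 2 called genes lay within 20 Mb, Crb1 (139197056 to 139377100) and Ipo9 (135382312 to 135430499). They were 2 of 16 called genes with a position, against 135 of 13987 tested genes with a position. Ipo9, an importin, was at 39.5 ± 0.665 FPKM in OIR KO against 27.6 ± 0.415 in OIR WT (log2 0.51, SE 0.08, adjusted p = 0.0489), and it lost its call without any 1 of the 6 libraries (0.0709 to 0.277).

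**Figure D2:**
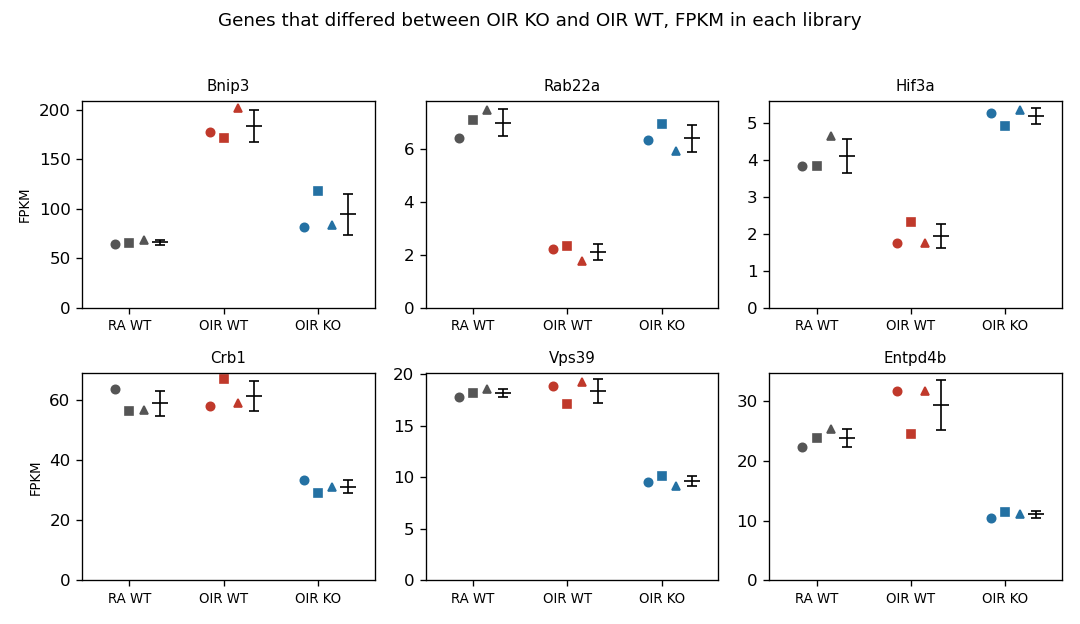
FPKM of 6 genes in each library of RA WT, OIR WT and OIR KO; circles, squares and triangles stand for replicates 1, 2 and 3, and bars for the mean ± SD of a group. Rab22a and Hif3a lie lower in every OIR WT library than in every OIR KO library, Bnip3 lies lower in OIR KO than in OIR WT, and Crb1, Vps39 and Entpd4b lie lower in every OIR KO library than in every wild-type library.

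Most hypoxia response and glycolysis genes had lower means in OIR KO. Of 36 members, 32 had a negative log2 difference, with a median of -0.49, and 27 were lower when adjusted over the list alone. Bnip3 was the 1 member called over all genes, and the list was called (camera adjusted p = 8.46e-24; adjusted p = 0.221 with an estimated correlation). Fry gave an adjusted p of 0.0212. Relative to the RA WT mean, the list's mean log2 level was 0.372, 0.630 and 0.309 in OIR KO 1, 2 and 3 (0.44 ± 0.17) and 0.887, 0.828 and 1.035 in the OIR WT libraries (0.92 ± 0.11), with an exact two-sided permutation p of 0.1, the smallest possible with n = 3. The means of the pan-endothelial, Müller and horizontal lists did not overlap between these groups either. Pdk1, which diverts pyruvate from the mitochondria, was at 15.5 ± 3.27 FPKM in OIR KO and 28.7 ± 2.54 in OIR WT (log2 -0.89, SE 0.14, adjusted p = 0.0665). Immediate early genes had a median of -0.39 (camera adjusted p = 4.60e-05; adjusted p = 0.583 with an estimated correlation). Of its 20 members 0 were called by either adjustment, over all genes or adjusted over the list alone, and Jun was at 32.1 ± 4.97 against 45.7 ± 9.07 FPKM (log2 -0.50, adjusted p = 0.338).

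Pan-endothelial markers had a median of 0.37, with 0 of 22 members called over all genes and 4 higher when adjusted over the list alone (camera adjusted p = 1.46e-06; adjusted p = 0.530 with an estimated correlation). Ly6c1 was at 6.01 ± 0.415 FPKM in OIR KO and 3.69 ± 0.848 in OIR WT (log2 0.65, SE 0.14, adjusted p = 0.179), below the 17.0 ± 1.31 of RA WT. Müller glia markers had a median of 0.26, with 0 of 20 members called over all genes and 6 higher and 1 lower when adjusted over the list alone (camera adjusted p = 4.49e-05; adjusted p = 0.349 with an estimated correlation). Aqp4, the water channel of Müller end-feet, was at 16.4 ± 1.36 FPKM in OIR KO, 9.70 ± 2.12 in OIR WT and 21.6 ± 3.31 in RA WT (log2 0.74, SE 0.16, adjusted p = 0.169 against OIR WT). Interferon response genes had a median of 0.32 and 0 of 28 called members by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 4.60e-05; adjusted p = 0.759 with an estimated correlation). Gbp3, a guanylate-binding protein, was at 3.19 ± 0.958 against 1.58 ± 0.192 FPKM (log2 0.80, adjusted p = 0.243). That list was not called without OIR KO 2 (adjusted p = 0.314), the library with the highest list mean, 1.439 above RA WT. The mean difference of the interferon list was 0.095 without OIR KO 2, against 0.318 with all libraries.

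Retinal ganglion cell markers had a median of -0.18, with 0 of 22 members called over all genes and 1 lower when adjusted over the list alone. That member was Nefh, at 17.3 ± 1.58 FPKM in OIR KO against 28.1 ± 3.09 in OIR WT (log2 -0.68, SE 0.12, adjusted p = 0.0801 over all genes). The list's camera adjusted p was 0.000242 (adjusted p = 0.633 with an estimated correlation). Horizontal cell markers had a median of -0.18 (camera adjusted p = 0.0214; adjusted p = 0.349 with an estimated correlation; fry adjusted p = 0.0405). Reactive gliosis genes and STAT3 targets had a median of -0.52 (camera adjusted p = 0.000514; adjusted p = 0.831 with an estimated correlation). Lif, a cytokine of Müller glia, was at 0.945 ± 0.819 FPKM in OIR KO and 2.85 ± 2.08 in OIR WT (log2 -1.19, adjusted p = 0.447). Erythrocyte markers had a median of -1.61 (camera adjusted p = 0.00654; adjusted p = 0.633 with an estimated correlation). Lens markers had a median of 1.18 (camera adjusted p = 0.0180; adjusted p = 0.764 with an estimated correlation). Retinal pigment epithelium markers had a median of 0.37 (camera adjusted p = 0.0122; adjusted p = 0.759 with an estimated correlation), and ciliary body, iris and cornea markers of 0.33 (camera adjusted p = 0.0143; adjusted p = 0.583 with an estimated correlation). In these lists 0 members were called over all genes, and 0 when adjusted over the list alone apart from Nefh. Without OIR KO 2 the ganglion (adjusted p = 0.270), horizontal (0.155), lens (0.620) and ciliary (0.0930) lists were not called. The mean lens difference was 0.27 without OIR KO 2, against 0.925 with all libraries. The gliosis list was not called without OIR KO 3 (0.213) or OIR WT 3 (0.111), and the erythrocyte list not without OIR KO 3 (0.0565) or OIR WT 3 (0.0930). The mean gliosis difference was -0.206 without OIR KO 3 and -0.279 without OIR WT 3, against -0.521 with all libraries. The pigment epithelium list was not called without OIR KO 1 (0.134) or OIR WT 1 (0.15), and the ciliary list not without OIR WT 1 (0.102).

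The other 14 lists were not called between OIR KO and OIR WT. Markers of tip cells had a median of -0.09 (camera adjusted p = 0.185), pericytes -0.09 (0.216), microglia and macrophages -0.09 (0.0970), alternative macrophage activation -0.08 (0.581) and proinflammatory cytokines and chemokines -0.08 (0.529). Rod markers had a median of 0.01 (0.511), cone markers -0.04 (0.529), cell cycle genes -0.06 (0.494), cholesterol synthesis genes -0.04 (0.529) and mitochondrially encoded genes 0.08 (0.494). For complement (median -0.02, mean 0.02; 0.615), bipolar cells (-0.02, 0.06; 0.494), amacrine cells (0.02, -0.03; 0.548) and extracellular matrix (0.00, -0.14; 0.494), median and mean differed in sign. When adjusted over the list alone, 0 members of these lists other than complement were called. Cd8a, the only tested gene of the neutrophil and lymphocyte list, had a log2 difference of -0.14 (adjusted p = 0.816). In total 12 of 26 lists were called, 6 upwards and 6 downwards, with 0 called with an estimated correlation and 2 by fry.

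**Figure D3:**
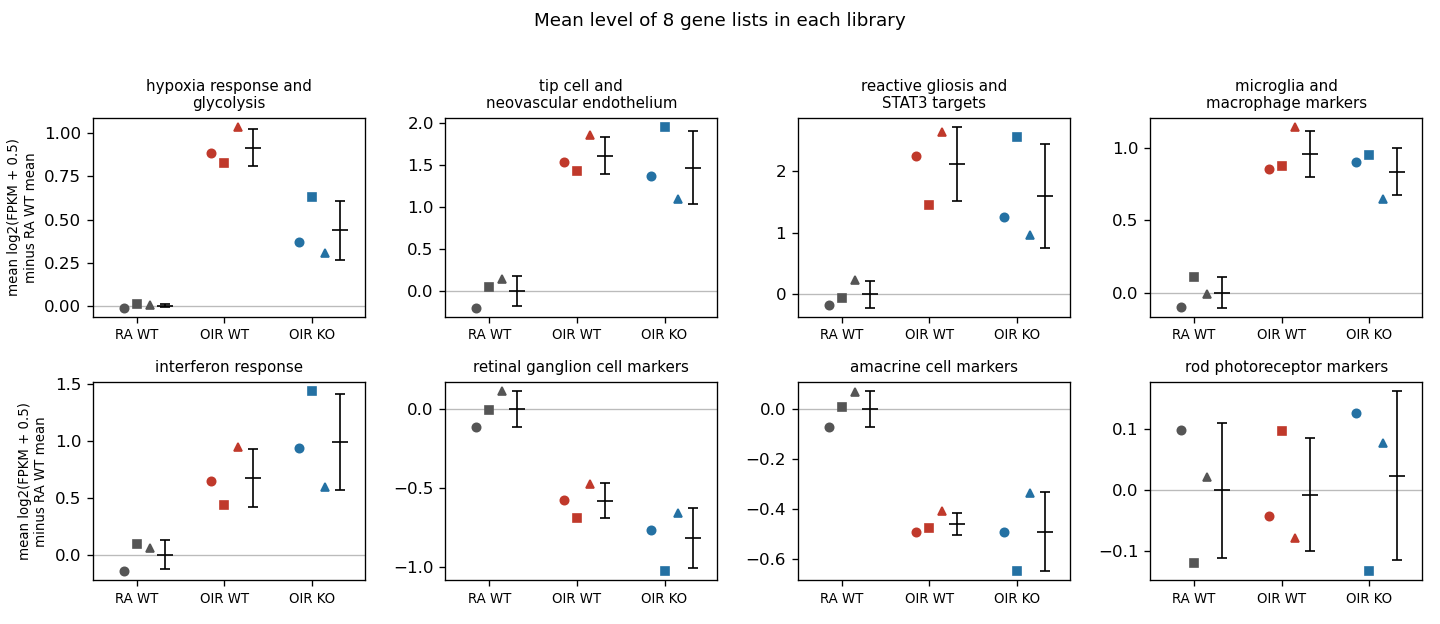
Mean log2(FPKM + 0.5) of the members of 8 gene lists in each library, minus the RA WT mean; circles, squares and triangles stand for replicates 1, 2 and 3, and bars for the mean ± SD of a group. The hypoxia list lies at 0.309 to 0.630 in the OIR KO libraries and at 0.828 to 1.035 in the OIR WT libraries, whereas the groups overlap in the gliosis and microglia lists.

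Against RA WT, the OIR KO group differs in both exposure and genotype. Edn2 was at 61.9 ± 58.5 FPKM in OIR KO (log2 5.15, SE 0.72, adjusted p = 0.00618), Adm at 19.9 ± 13 FPKM (log2 3.88, SE 0.37, adjusted p = 0.00180), and Ndufa4l2 at 112 ± 26.4 FPKM (log2 4.25, SE 0.20, adjusted p = 3.02e-05), all higher than in RA WT. A2m, a protease inhibitor of reactive glia (log2 3.30, SE 0.51), and Lad1 (log2 3.31, SE 0.68) were the other leading risen genes. Cck, the neuropeptide cholecystokinin, fell from 23.3 ± 1.91 FPKM to 5.74 ± 0.969 FPKM (log2 -1.94, SE 0.14, adjusted p = 0.000439), followed by Slco1a4 (log2 -1.81), Xlr3b (log2 -1.80), Duxbl2, from a family of copies (log2 -1.69), and Nrn1, a neurite growth gene (log2 -1.64). Without 1 library, calls were lost for Lad1 (without RA WT 1, 2 or 3 or OIR KO 1, adjusted p = 0.0566 to 0.0643), Xlr3b (without RA WT 2 or 3 or OIR KO 1 or 2, 0.0637 to 0.118) and Nrn1 (without RA WT 2, 0.0541, or RA WT 3, 0.0687).

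In total 1636 genes changed, 744 upwards and 892 downwards, of which 286 rose and 117 fell at least 2-fold, and 32.7% of genes had no overlap between the groups, where chance gives 10%. The number was 1066 without RA WT 2, 697 without RA WT 3, 709 without OIR KO 1 and 732 without OIR KO 2, against 1203 without RA WT 1 and 1792 without OIR KO 3. It was 1090 when only these 2 groups were fitted, and 518 without RA WT 1 and OIR KO 2, the libraries with the most lens RNA, an alternative chosen after seeing the data. Of 26 lists 19 were called, 13 upwards and 6 downwards, with 0 called with an estimated correlation and 17 by fry.

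Hypoxia response and glycolysis genes rose in 8 of 36 members and fell in 2, Aldoc (log2 -0.37) and Hk2 (log2 -0.54), or 13 and 2 when adjusted over the list alone. The list's median was 0.26 (camera adjusted p = 1.15e-05; adjusted p = 0.286 with an estimated correlation). Vegfa rose to 199 ± 42.7 FPKM (log2 1.54, SE 0.14, adjusted p = 0.000868). Aldoc was not called without RA WT 2, RA WT 3, OIR KO 1 or OIR KO 2 (0.109 to 0.144), and Hk2 not without RA WT 1, RA WT 3, OIR KO 1 or OIR KO 2 (0.0645 to 0.0847). Tip cell markers rose in 21 of 27 members, or 25 when adjusted over the list alone. Their median was 1.43 (camera adjusted p = 1.38e-17; adjusted p = 0.188 with an estimated correlation), with Apln at 25.6 ± 12.1 FPKM (log2 3.02) and Prnd at 3.97 ± 1.34 FPKM (log2 2.87). Pan-endothelial markers rose in 11 of 22 members and fell in 2, Ly6c1 (log2 -1.42) and Slco1a4, or 12 and 3 when adjusted over the list alone. The endothelial median was 0.67 (camera adjusted p = 0.00305; adjusted p = 0.368 with an estimated correlation), and the list was not called without the 2 libraries with the most lens RNA (adjusted p = 0.0514). Pericyte markers rose in 4 of 15 members, Higd1b (log2 1.60), Acta2 (log2 1.42), Cspg4 (log2 1.01) and Rgs5 (log2 1.01), or 11 when adjusted over the list alone. The pericyte median was 0.70 (camera adjusted p = 4.20e-05; adjusted p = 0.235 with an estimated correlation). Acta2 lost its call without RA WT 1, RA WT 2, RA WT 3, OIR KO 1 or OIR KO 2 (0.0619 to 0.102).

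Among immune lists, microglia and macrophage markers rose in 15 of 26 members, or 19 when adjusted over the list alone (median 0.83, camera adjusted p = 4.52e-12; adjusted p = 0.174 with an estimated correlation). Interferon response genes rose in 14 of 28 members, or 26 when adjusted over the list alone (median 0.94, camera adjusted p = 5.76e-13; adjusted p = 0.235 with an estimated correlation). Complement genes rose in 10 of 18 members, or 14 when adjusted over the list alone (median 0.76, camera adjusted p = 1.08e-08; adjusted p = 0.188 with an estimated correlation). Irf7, a transcription factor of the interferon response, rose to 27.2 ± 6.07 FPKM (log2 1.84, SE 0.16, adjusted p = 0.000868), and C1qb to 14.4 ± 1.62 FPKM (log2 1.61, SE 0.12, adjusted p = 0.000439). Of 13 cytokines and chemokines, Icam1, an adhesion molecule (log2 1.48), and Ccl3 (log2 1.08) rose, or 6 when adjusted over the list alone. The cytokine median was 0.86 (camera adjusted p = 0.00148; adjusted p = 0.331 with an estimated correlation), and the list was not called when only these 2 groups were fitted (adjusted p = 0.17). Of 6 genes of alternative activation, Stab1 (log2 1.5) and Tgfb1 (log2 1.18) rose by either adjustment, over all genes or adjusted over the list alone. That list was called (camera adjusted p = 0.0348; adjusted p = 0.331 with an estimated correlation), but not without RA WT 2 (0.0663) or OIR KO 2 (0.0766). Ccl3 (0.0714 to 0.116) and Tgfb1 (0.0632 to 0.0982) lost their calls without RA WT 1, RA WT 2, RA WT 3, OIR KO 1 or OIR KO 2. Cd8a, the only tested gene of the neutrophil and lymphocyte list, was at 0.777 ± 0.138 FPKM (log2 0.51, adjusted p = 0.0615). It was higher when adjusted over the list alone, which for a single tested gene is no adjustment.

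Reactive gliosis genes rose in 10 of 33 members, or 20 when adjusted over the list alone (median 1.60, camera adjusted p = 4.62e-10; adjusted p = 0.319 with an estimated correlation). Cell cycle genes rose in 13 of 22, or 15 when adjusted over the list alone (median 0.70, camera adjusted p = 9.83e-09; adjusted p = 0.188 with an estimated correlation). Extracellular matrix genes rose in 17 of 33 with Mmp9 (log2 -0.82) fallen, or 23 and 1 when adjusted over the list alone. The matrix median was 0.59 (camera adjusted p = 4.55e-10; adjusted p = 0.235 with an estimated correlation). Immediate early genes rose in 8 of 20, or 11 risen and 2 fallen when adjusted over the list alone (median 0.67, camera adjusted p = 0.000108; adjusted p = 0.303 with an estimated correlation). Nr4a1 rose from 24.6 ± 2.94 to 81.0 ± 12 FPKM (log2 1.70, SE 0.14). Cholesterol synthesis genes fell in 7 of 24, or 14 when adjusted over the list alone (median -0.35, camera adjusted p = 1.08e-08; adjusted p = 0.188 with an estimated correlation), with Insig1 at 10.5 ± 2.22 FPKM (log2 -1.24, SE 0.14).

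Ganglion cell markers fell in 14 of 22 members, or 20 when adjusted over the list alone (median -0.75, camera adjusted p = 7.43e-15; adjusted p = 0.174 with an estimated correlation). Nefl was at 64.7 ± 15.5 FPKM (log2 -1.44, SE 0.17, adjusted p = 0.00235). Amacrine cell markers fell in 13 of 25, or 16 when adjusted over the list alone (median -0.47, camera adjusted p = 8.26e-11; adjusted p = 0.174 with an estimated correlation). Gad1, a GABA-synthesising enzyme, fell from 81.7 ± 1.95 to 43.3 ± 6.90 FPKM (log2 -0.92, SE 0.12). Bipolar cell markers fell in 7 of 26, with 13 fallen and 1 risen when adjusted over the list alone (median -0.26, camera adjusted p = 2.11e-06; adjusted p = 0.235 with an estimated correlation). Horizontal cell markers fell in 4 of 12, Nefm (log2 -1.49), Calb1 (log2 -0.83), Lhx1 (log2 -0.70) and Slc4a3 (log2 -0.48), or 5 when adjusted over the list alone. The horizontal median was -0.39 (camera adjusted p = 0.000549; adjusted p = 0.174 with an estimated correlation). Cone markers fell in 3 of 17 by either adjustment, over all genes or adjusted over the list alone, Rxrg (log2 -0.76), Slc24a2 (log2 -0.64) and Gulo (log2 -0.49). The cone median was -0.26 (camera adjusted p = 0.00805; adjusted p = 0.360 with an estimated correlation). Without 1 library, calls were lost for Lhx1 (without RA WT 1, RA WT 3, OIR KO 2 or OIR KO 3, adjusted p = 0.0816 to 0.134), Slc4a3 (without each but OIR KO 3, 0.0520 to 0.0841) and Rxrg (without RA WT 3, 0.0566). They were also lost for Gulo (without each but OIR KO 1, 0.0520 to 0.113) and the cone list (without OIR KO 2, 0.0531).

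The Müller list did not pass (median -0.29, camera adjusted p = 0.0573; adjusted p = 0.381 with an estimated correlation). Among its 20 members Slc6a11 (log2 -0.72), Abca8a (log2 -0.96), Kcnj10 (log2 -0.61) and Dkk3 (log2 -0.46) fell and Crym (log2 1.60) rose, or 7 and 4 when adjusted over the list alone. Of these, Slc6a11 kept its call without each library in turn. Abca8a lost it without RA WT 2, RA WT 3 or OIR KO 2 (adjusted p = 0.0611 to 0.0709), and Kcnj10 without RA WT 3 (0.0511) or OIR KO 1 (0.0506). Dkk3 lost it without RA WT 2, RA WT 3, OIR KO 1 or OIR KO 2 (0.0957 to 0.118) and Crym without each but OIR KO 3 (0.0728 to 0.106). Rod markers (camera adjusted p = 0.961), retinal pigment epithelium markers (0.461), lens markers (0.461), erythrocyte markers (0.404), ciliary body markers (0.315) and mitochondrially encoded genes (0.234) were not called. The rod list had a median of -0.02 and a mean of 0.02. In these 6 lists, 1 gene was called, Opn4, the melanopsin of intrinsically photosensitive ganglion cells (log2 -1.08), over all genes and when adjusted over the list alone. Its call was lost without RA WT 2 (0.0530), RA WT 3 (0.0636), OIR KO 1 (0.0619) or OIR KO 2 (0.0568).

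Both groups with retinopathy were compared with the same RA WT libraries, so their changes share chance values. Of the genes changed in both comparisons, 554 rose in both and 685 fell in both, with 0 in opposite directions, where independent lists of these sizes share 59.8 and 70.7. Part of the excess of these counts over independent lists may come from the shared controls. In 10 simulations of unchanged groups against shared controls 0 calls were shared. Groups without changes give few calls to share, so that count cannot show how large this part is. Across the 15678 genes, which are not independent replicates, the log2 changes correlated with r = 0.83 against 0.50 in simulation, 79.8% had the same sign against 66.7%, and the covariance was 0.1762 against 0.0247, a difference of 0.1515.

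On genes that changed in retinopathy, the OIR KO libraries lay closer to room air than the held-out OIR WT library by a mean of 15.7% of the retinopathy change over 3 rotations, a value with no test. It was 24.1% on 1039 genes with OIR WT 1 held out, 1.92% on 2164 genes with OIR WT 2 held out and 21.2% on 1331 genes with OIR WT 3 held out. The held-out OIR WT 2 itself lay 0.23 (log2, median over genes) back towards room air from the other OIR WT libraries, on a change of 0.83, against -0.02 for OIR WT 1 and 0.01 for OIR WT 3. From the held-out OIR WT 2, the OIR KO mean lay only 0.016 further back, against 0.216 from OIR WT 1 and 0.176 from OIR WT 3. OIR WT 2 thus lay nearly as far back as the OIR KO mean. The shift is therefore not separated from the spread between OIR WT libraries. The mean was 29.9% without OIR KO 2 and 4.30% without OIR KO 3.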

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

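The fits of genes with an Ensembl ID and the fits without the 2 libraries with the most lens RNA were chosen after seeing the data. For OIR WT against RA WT, 1581 genes were called with the sex covariate, and 1039 to 2164 when single libraries were left out, against 2503. For OIR KO against OIR WT, against 21 genes, 13 were called at a mean FPKM of at least 1, 13 without trend and robust option, 459 with array weights, 8 with the replicate number as a block and 13 among Ensembl genes, where fewer genes were tested. Leaving out single libraries gave 7 to 42. For OIR KO against RA WT, against 1636 genes, 1081 were called with the block, 1090 when only the 2 groups were fitted, 518 without the lens libraries, where fewer samples were used, and 697 to 1792 when single libraries were left out. Apart from smaller numbers of genes or samples, the cause was not tested.

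With an estimated correlation 0 lists were called in each comparison, against 22, 12 and 19, and fry called 2 for OIR KO against OIR WT. With camera at the preset correlation, the 53 list calls had 1060 values under the other fits, of which 1017 kept direction and call and 43 lost the call. In each of these fits 36 list calls were kept, but 0 with an estimated correlation. Apart from single libraries left out, calls were lost as follows. For OIR WT against RA WT, they were lost for alternative macrophage activation without the filter (adjusted p = 0.13), cone and lens markers with quantile normalization (0.0643 each), lens markers in the fit of 2 groups (0.185), and cone (0.0799) and lens markers (0.399) without the lens libraries. Between OIR KO and OIR WT, they were lost for horizontal cells at a mean FPKM of at least 1 (0.164), lens markers with array weights (0.181) and in the fit of 2 groups (0.745), and, without the lens libraries, interferon (0.331), horizontal (0.173), ganglion (0.307), lens (0.631) and ciliary lists (0.0788). Between OIR KO and RA WT, they were lost for cytokines in the fit of 2 groups (0.17) and, without the lens libraries, pan-endothelial (0.0514) and cone markers (0.143). Of 3300 values of 166 gene calls, counting a gene once per comparison, for genes of the rule and others named in the text, 2830 kept direction and call, 470 lost the call and 0 reversed. For Il10rb, OIR KO against OIR WT gave -0.02 with no call, and it lay between -0.132 and 0.084 when single libraries were left out, above 0 without OIR KO 3, OIR WT 1 or OIR WT 3.

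The shift back towards room air was 4.30% to 29.88% when single libraries were left out, and the mean level of Il19 was 0 to 0.0051 FPKM. Deviations of libraries with the same replicate number correlated across genes with r from -0.353 to 0.134, so the numbers did not pair the samples. Depth is unknown, so the precision of low values cannot be given.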

Other observations

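The test of summed Entpd4 copies, the Nnt ratio, the count of called genes near Il19 and the gliosis covariate were chosen only after the results they address were seen.

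Libraries of a retinopathy group differed from one another in several lists. The mean log2 level of reactive gliosis genes relative to RA WT was 1.258, 2.552 and 0.961 in OIR KO 1, 2 and 3 and 2.252, 1.453 and 2.629 in OIR WT 1, 2 and 3. Erythrocyte markers were at 0.021, 1.845 and -0.006 in OIR KO and at 1.949, 1.167 and 2.244 in OIR WT. Lens markers were at 1.372 in RA WT 1 and 0.994 in OIR KO 2, and at most -0.334 in the other libraries. Families of near-identical copies, chosen after their values were seen, also differed: the summed FPKM of Tmem254 copies in OIR KO was 0.356 of its mean in the wild-type libraries, that of Duxbl copies 0.282 and that of Dynlt1 copies 1.468, with each OIR KO library outside the range of the 6 wild-type libraries.

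Of the 21 genes that differed between OIR KO and OIR WT, 11 also differed from RA WT in the same direction, 3 higher and 8 lower, among them Crb1, Vps39 and Entpd4b. Reads moved between near-identical copies were argued against for Entpd4b and Gm16867, since the summed Entpd4 copies lay between 18.9 and 21.6 FPKM in OIR KO and between 48.0 and 66.9 FPKM in the wild-type libraries, a ratio of 0.373. DNA of another strain in the knockout line stays open: the summed Nnt entries, which differ between substrains of C57BL/6, had a ratio of 1.08 between OIR KO and RA WT, which speaks only for that locus. Genes within 20 Mb of Il19 had an odds ratio of 1.15 for an unadjusted p under 0.05 (0.621 to 1.98, Fisher's exact two-sided p = 0.563), and 1 of the 11 genes, Crb1, lay there; among all called genes, 2 of 16 with a position lay there against 135 of 13987 tested (odds ratio 14.9, Fisher's exact two-sided p = 0.0102), but this count was made after both were seen and includes Ipo9, which is not among the 11 and lost its call without any 1 library. Only the region around Il19 was tested for position. Elsewhere, the called genes Entpd4b (start 69555424), Gm16867 (69363504) and Tmem254a (25923300), all from families of copies, lay on chromosome 14. Strain DNA may account for part of these differences, and an effect of the loss of IL-19 was not tested apart from it.

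The hypoxia list was lower in each OIR KO library than in each OIR WT library, with a mean log2 difference of -0.48 (SE 0.12). Scaling of the libraries was argued against, as the difference nearest 0 under 3 scalings was -0.468, and so was the sex of the animals, with -0.465 under the Y-linked covariate. With the gliosis list as a covariate in the 6 OIR libraries, the difference was -0.382 (SE 0.037, 95% interval -0.498 to -0.266), 79.6% of its size. This argues against a milder retinopathy, as gliosis measures it, as the whole cause, and a part stays open. Loss of IL-19, strain DNA and differences in vessel regrowth were not tested as causes. Separation of every library was not particular to the hypoxia list. Among single genes, 17.7% had no overlap between these groups, where chance gives 10%. List means in OIR KO also lay wholly above OIR WT for pan-endothelial (0.213 to 0.679 against -0.186 to 0.169) and Müller markers (-0.106 to -0.013 against -0.387 to -0.178). For horizontal cell markers they lay wholly below OIR WT (-0.459 to -0.343 against -0.226 to -0.172).

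The 10 splits of 6 libraries into 3 and 3, the real grouping included, are too few for a share under 0.05. For OIR WT against RA WT, 1 of 10 splits, the real grouping itself, gave 2503 genes or more, and the highest other gave 2. For OIR KO against OIR WT, 2 of 10, the real grouping and another, gave 21 or more, and that other gave 348. That split, OIR KO 1, OIR KO 3 and OIR WT 2 against the rest, points to a structure of the samples. Their gliosis list means relative to RA WT were 1.258, 0.961 and 1.453. Those of OIR KO 2, OIR WT 1 and OIR WT 3 were 2.552, 2.252 and 2.629. On the leading principal component they lay at 7.96, -3.3 and 11.7, against 32.5, 28.9 and 31.3. The split thus followed the gliosis level of the libraries, across genotypes, and its cause was not tested. For OIR KO against RA WT, 1 of 10, the real grouping itself, gave 1636 or more, and the highest other gave 1.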
